A study of Sus scrofa with 6 samples.

How the data were processed

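The 6 libraries were grouped by their titles and treatment labels into control (3 libraries, 0.1% ethanol) and RA (3 libraries, 2 umol/L all-trans-retinoic acid). The labels name total RNA from testis and give no extraction protocol. The aligner, the counting tool, its strand setting, the genome build and the authors' statistical test are not given in the sources used here.

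The authors deposited a table of FPKM values (fragments scaled to gene length and library total) for 29884 genes, each with a length, a gene type and coordinates, per the file headers. They also deposited tables of whole-number counts per library for the genes they called, with a log2 fold change of RA over control, a p-value and an FDR, per the file headers. Every listed FDR is under 0.05, and the sign of the log2 fold change matched the counts in 4377 of 4377 genes. FPKM multiplied by the deposited length and a library total gave whole reads (within 0.05) for 99.8% to 99.9% of the non-zero values of a library, where each total was the median over genes with both values. Reads of 42 genes were not whole in every library and were left out of the count tests. Low values rest on few reads: CYP26A1 had 45, 64 and 14 recovered reads in control replicates 1, 2 and 3, against 3893, 3737 and 2337 in RA replicates 1, 2 and 3. Pairs of replicates of a group differed by far more than sampling noise, with a mean chi-square per gene between 18.8 and 138, so no library was counted as a copy of another.

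Coordinates are those of the authors' table. Of 29862 symbols found in the RefSeq annotation of the Duroc pig assembly that was supplied, 92.7% had the same chromosome, start and end there, but the sources used here do not name the authors' build. No reference sequence was used. List genes that the table holds under an older symbol, or as a LOC row with the only best human match of that name, were matched to that row, and 625 of 645 list genes were found.

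Genes with a mean of at least 0.5 FPKM over the 6 libraries were kept (14567, of which 13674 protein-coding). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a pseudocount of 1, a variance trend and group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. FPKM is not a count, so count tests were run only as alternatives. Gene lists were tested with camera at a preset correlation of 0.01 and the same variance trend, adjusted over the 27 of 28 lists with at least 5 measured members; the list left untested holds haemoglobin genes. None of the 9 called lists held with an estimated correlation. Some lists share genes, for example REC8, SYCP3, EGR2 and THY1. Exact permutation of 3 against 3 libraries cannot give p under 0.1, so no single-gene permutation test was run.

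The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Camera was first run without the variance trend of the limma fit, which called 5 higher and 3 lower lists. The setting was changed after that result was seen, to match the limma fit fixed beforehand, and it added the oxidative phosphorylation list to the calls. The rule names the 10 genes with the largest rise and the 10 with the largest fall that have a symbol, a limma adjusted p under 0.05, a mean of at least 1 FPKM in the higher group and no overlap between groups. It adds 20 genes of retinoid response and spermatogonia (CYP26A1, CYP26B1, RARB, DHRS3, STRA8, KIT, SOHLH1, REC8, DNMT3B, GFRA1, ZBTB16, UCHL1, NANOS2, ID4, SYCP3, DDX4, SOX9, STAR, ACTA2, MKI67), up to 4 members of smallest p per list, and the 3 lncRNAs with the largest rise and fall. The minimum of 200 bases for lncRNAs was chosen after seeing the files. Genes outside the rule were chosen after their values were seen, and the text says so where it gives their values. Some genes that the rule takes are not reported here.

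Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of mean FPKM 1, a filter of mean FPKM 0.1 for lncRNAs, median-ratio scaling, quantile normalization, limma without trend, with robust moderation and with array weights, a fold threshold, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a lowess correction of each library for log2 gene length (span 0.3), and no minimum length for lncRNAs. The length correction takes out any trend with length in a library, including an RA effect that follows length. A call lost after it does not tell a technical trend from such an effect. edgeR called 3650 genes, and its log2 fold changes correlated with those in the authors' deposited tables at r = 1.000 across 4045 genes, which are not independent replicates.

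The limma step was tested on simulated data with counts for 14431 genes drawn from the means and totals of the real libraries at a fixed negative binomial dispersion, which was not estimated from the data and leaves out RA replicate 2's distance from the other libraries. It recovered 45.2% of 62 genes changed 1.5-fold, 97.0% of 67 changed 2-fold and 100% of 64 changed 4-fold. Of 173 calls in all, 16 were among the 14238 unchanged genes. That share of false calls was above the adjusted p threshold in this simulation. Camera called the 1 changed list and 0 of the unchanged lists. The simulated counts held no correlation among the genes of a list, so this result does not test camera's preset correlation. The shares of recovered genes hold only for this dispersion and this number of changed genes. In the real data, ATP5A1 passed limma at a ratio of mean FPKM of 1.20. Figures were drawn with matplotlib 3.10.9.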

Results

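RNA sequencing measured transcript abundance in 6 libraries from cultures of porcine (Sus scrofa) testis cells that the labels call primitive spermatogonia, the germ cells from which sperm production starts. Cultures received 2 umol/L all-trans-retinoic acid (RA), the vitamin A derivative that drives spermatogonia towards meiosis in mammals, or its solvent, 0.1% ethanol, as control. Each group held 3 libraries. The read totals behind the FPKM values were 79752197, 75747247 and 62084199 reads in control replicates 1, 2 and 3 and 87520891, 73176464 and 63836470 in RA replicates 1, 2 and 3. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The series text also names comparisons with the process in vivo and with mice, which were not analysed here.

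The comparison of RA with control asked which genes respond to RA in vitro. Of 14567 genes kept, 2019 were higher and 1750 were lower in RA (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05), which is 25.9% of the genes. The log2 change reached 1 or more in 177 of the higher and 212 of the lower genes. In 6985 genes (48.0%) the 3 RA libraries did not overlap the 3 control libraries, where chance gives 10% of genes. Log2 changes here and below are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Leaving out a library moved the higher count by over 1.5 times in 3 cases, to 1336 without control replicate 1, 1201 without control replicate 2 and 1235 without control replicate 3. The lower count moved so in 2 cases, to 992 without control replicate 2 and 1107 without control replicate 3.

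RA replicate 2 stood apart from the other RA libraries. Its mean correlation with them was 0.984, against 0.991 for RA replicate 1 and 0.989 for RA replicate 3, and the control libraries lay between 0.994 and 0.995. These correlations are across genes, which are not independent replicates. The first component of the log values separated RA from control and carried 71.3% of the variance, while the second (17%) separated RA replicate 2 from RA replicates 1 and 3. RA replicate 2 also lay apart on the first component, with a score of 40.2 against 18.8 and 15.5 for RA replicates 1 and 3. Across genes, the log2 change in RA correlated with gene length (Spearman's rho = -0.32), and rho was -0.20 without RA replicate 2. Among genes of at most 1640 bases, 625 rose and 184 fell, and among genes of at least 5920 bases, 171 rose and 456 fell (limma).

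**Figure D1:**
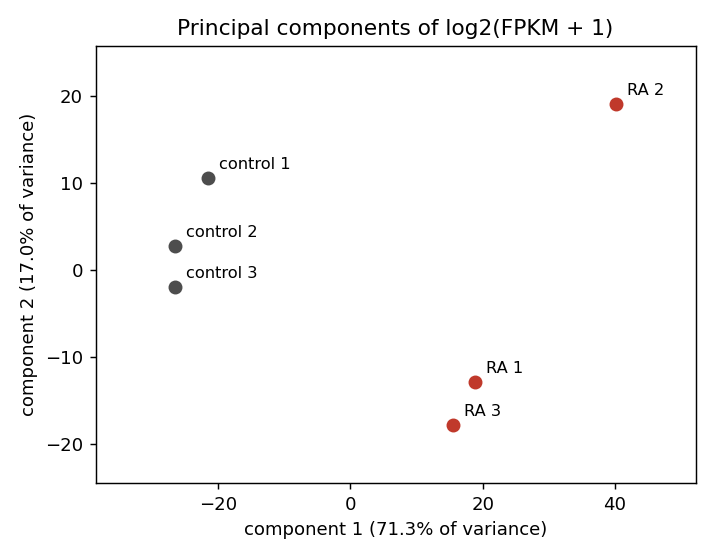
Principal components of the log2(FPKM + 1) values of 14567 genes, with 1 point per library (control in grey, RA in red) and the share of variance on each axis. The 3 control libraries lie on the left of component 1 (71.3% of variance). RA replicate 2 lies apart from RA replicates 1 and 3 along component 2 (17%) and also further right on component 1.

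DHRS3 and CYP26A1, which act in retinoid metabolism, were among the 10 genes with the largest rise. DHRS3, a retinaldehyde reductase that limits RA formation, rose from 1.28 ± 0.168 to 132 ± 12.5 FPKM (SD, n = 3 libraries per group, as in all such pairs below), a ratio of 103 and a log2 change of 5.86 ± 0.095 (SE, limma adjusted p = 9.69e-08). CYP26A1, a cytochrome P450 that degrades RA, rose from 0.144 ± 0.0818 to 11.6 ± 1.91 FPKM (log2 change 3.45, limma adjusted p = 6.21e-06). The lectin gene REG3G rose from 0.944 ± 0.0611 to 43.1 ± 1.73 FPKM, the WNT ligand WNT6 from 2.30 ± 0.774 to 55.8 ± 13.1, the endothelin EDN2 from 1.32 ± 0.423 to 31.4 ± 5.76, and the activin-binding FSTL3 from 10.7 ± 0.893 to 143 ± 14.0. HTRA4 (log2 change 3.60), the haptoglobin gene HP (3.39), the relaxin gene RLN2 (3.36) and the proteoglycan decorin, DCN (2.88), completed the 10 largest rises. Limma adjusted p-values of these 10 genes were at most 2.13e-05.

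The largest fall on the log2(FPKM + 1) scale was that of IGFBP5, an insulin-like growth factor binding protein, from 297 ± 18.8 to 19.0 ± 0.319 FPKM (log2 change -3.90 ± 0.064 SE, limma adjusted p = 9.69e-08). The water channel AQP5 fell from 67.0 ± 4.22 to 6.37 ± 2.13 FPKM and the testosterone-forming enzyme HSD17B3 from 14.0 ± 2.36 to 0.827 ± 0.326. By the ratio of mean FPKM, HSD17B3 fell more than IGFBP5 (17 against 15.7). GLDN (log2 change -2.74), ENHO (-2.48), the adenylate kinase AK1 (-2.35), DCLK1 (-2.33), SYNPO2L (-2.21), the actin-bundling ESPN (-2.19) and MELTF (-2.18) also fell, with limma adjusted p-values of at most 0.000105. DHRS3 lies on chromosome 6, 72556234 to 72599233, CYP26A1 on chromosome 14, 104561394 to 104567099 and IGFBP5 on chromosome 15, 118861816 to 118877787, in the coordinates of the deposited table.

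Genes of retinoid metabolism and signalling rose as a list: 13 of 25 measured members rose and 3 fell (camera adjusted p = 0.00151, and adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone, 15 rose and 5 fell. RARB, an RA receptor and direct target of RA, rose from 1.18 ± 0.166 to 8.56 ± 0.197 FPKM (limma adjusted p = 1.17e-05), and the transglutaminase TGM2 rose from 77.5 ± 3.19 to 364 ± 28.5 (limma adjusted p = 2.68e-06). The row LOC100521659, whose best human match in the authors' table is CYP26B1, rose from 6.45 ± 1.18 to 14.0 ± 0.662 FPKM (limma adjusted p = 0.000821). Of the 3 members that fell, ALDH1A2, a retinaldehyde dehydrogenase, fell from 175 ± 8.13 to 51.0 ± 4.07 FPKM (limma adjusted p = 9.52e-06), and RDH11 and ALDH1A1, named after their values were seen, had log2 changes of -0.60 and -0.85.

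Of 10 measured HOX genes, body-axis transcription factors of which several respond to RA in embryos, 3 rose and 0 fell (5 rose and 0 fell adjusted over the list alone). Among them were HOXA4 (log2 change 0.96, limma adjusted p = 0.0101) and HOXB2 (0.46, 0.0122), each at a mean of at most 2.73 FPKM. The list was called higher (camera adjusted p = 0.0424), with an adjusted p = 0.635 with an estimated correlation. Its camera adjusted p was 0.0733 without control replicate 2, 0.0606 without RA replicate 1 and 0.0938 without RA replicate 2. It was 0.0574 with a pseudocount of 0.1, 0.293 with a filter of mean FPKM 1 and 0.0869 after a correction for gene length, an alternative chosen after seeing the data. HOXA4 had a limma adjusted p of 0.0503 and HOXB2 of 0.0546 without control replicate 2, and HOXB2 of 0.0541 without control replicate 3.

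**Figure D2:**
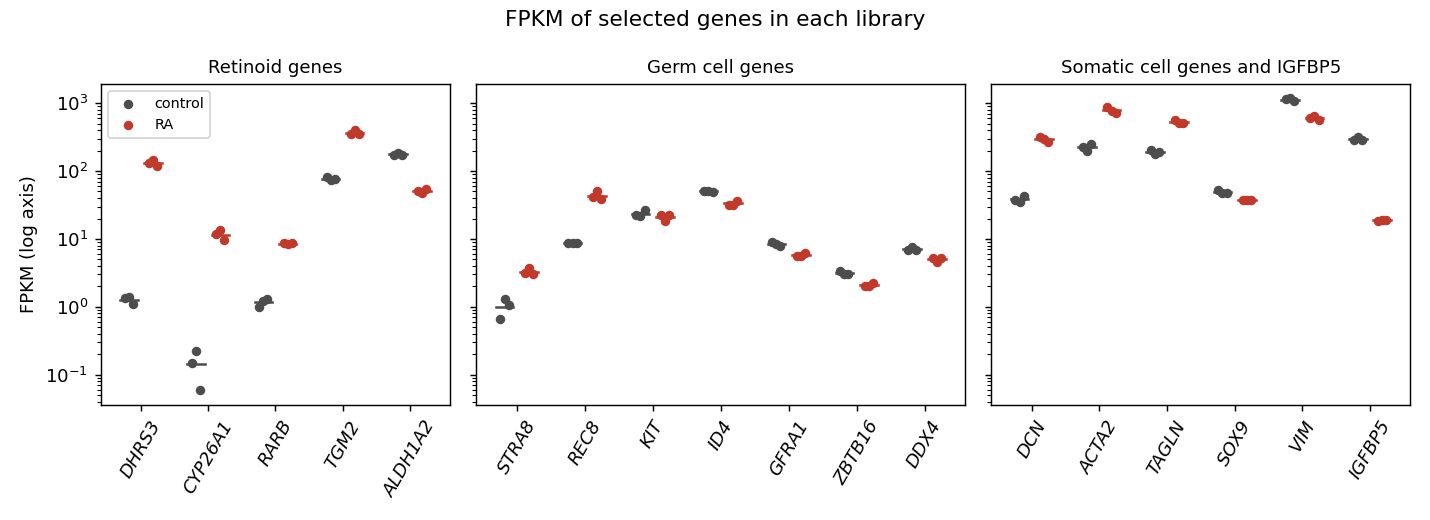
FPKM on a log axis of retinoid, germ cell and somatic cell genes and IGFBP5 in the 3 control (grey) and 3 RA (red) libraries; points are libraries and short lines are group means. DHRS3 moves from a mean of 1.28 to 132 FPKM and IGFBP5 from 297 to 19.0, while the control and RA libraries of KIT overlap.

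Germ cell genes moved in both directions. STRA8, a gene that RA induces before meiosis, rose from 1.01 ± 0.33 to 3.29 ± 0.337 FPKM (log2 change 1.10 ± 0.14 SE, limma adjusted p = 0.00126), and REC8, a meiotic cohesin, rose from 8.77 ± 0.105 to 43.5 ± 5.78 (2.18 ± 0.096, limma adjusted p = 1.12e-05). KIT, the receptor that marks differentiating spermatogonia, was at 23.7 ± 2.48 FPKM in control and 21.2 ± 2.30 in RA (limma adjusted p = 0.305), and SOHLH1 was at 16.3 ± 0.235 and 17.7 ± 3.89 (limma adjusted p = 0.615). DNMT3B (log2 change -0.09, limma adjusted p = 0.546) did not pass either. Of 17 genes of differentiating spermatogonia, STRA8, REC8 and the cyclin CCND2 (0.52) rose and 4 fell, among them DMRT1 (-0.71), and the list was not called (camera adjusted p = 0.739). Adjusted over the list alone, 3 rose and 5 fell, and the list's median (-0.093) and the direction of the test were lower while its mean (0.031) was higher.

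Of 30 measured genes of undifferentiated spermatogonia, 10 fell and 1, the syndecan SDC4 (log2 change 0.90), rose. Adjusted over the list alone, 13 fell and 2 rose. Which cells the transcripts of this list came from was not tested. The Sertoli cell gene CLU, named after its values were seen, was at a mean of 9242 FPKM in control. ID4, a marker of spermatogonial stem cells, fell from 50.3 ± 1.05 to 33.6 ± 2.77 FPKM (limma adjusted p = 0.00123), GFRA1, the receptor for the stem cell factor GDNF, from 8.36 ± 0.583 to 5.84 ± 0.384 (limma adjusted p = 0.00908), and ITGA6 from 71.5 ± 4.42 to 21.8 ± 5.92 (limma adjusted p = 0.000595). ZBTB16, encoding PLZF, fell from 3.18 ± 0.214 to 2.11 ± 0.135 (limma adjusted p = 0.0140), with limma adjusted p-values of 0.0550 without control replicate 1 and 0.0560 without RA replicate 1. After the correction for gene length the limma adjusted p was 0.0972 for GFRA1 and 0.101 for ZBTB16. UCHL1 was at 121 ± 5.23 FPKM in control and 105 ± 7.66 in RA (limma adjusted p = 0.0719, and 0.0101 without RA replicate 2), and NANOS2 at 1.16 ± 0.292 and 1.69 ± 0.438 (limma adjusted p = 0.155). The list as a whole was not called (camera adjusted p = 0.102); without RA replicate 2 its camera adjusted p was 0.0465, with array weights 0.0372, and fry gave an adjusted p of 0.0225.

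Genes expressed across germ cells were called lower as a list (camera adjusted p = 0.0424), with an adjusted p = 0.703 with an estimated correlation. Of 22 measured members, TDRD7, PIWIL2, DDX4, ASZ1 and TDRD6 fell and DAZAP1 rose, with limma adjusted p-values from 0.00780 to 0.0496, and adjusted over the list alone 7 fell and 1 rose. DDX4, the VASA helicase, fell from 7.10 ± 0.374 to 5.0 ± 0.386 FPKM (limma adjusted p = 0.0113, and 0.0573 without control replicate 2). TDRD6 and DAZAP1 were named after their values were seen. Without 1 library their calls (limma) were lost in 5 of 6 cases each, with adjusted p-values from 0.0560 to 0.115 for TDRD6 (the call held without RA replicate 2) and from 0.0544 to 0.168 for DAZAP1 (it held without RA replicate 3). ASZ1 had 0.0949 without control replicate 2 and 0.0846 without control replicate 3. The list's camera adjusted p rose to 0.0733 without control replicate 2, 0.0531 without control replicate 3, 0.0698 without RA replicate 1 0.0691 without RA replicate 3 and 0.0656 after the correction for gene length.

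Meiotic and later germ cell lists were not called. Of 21 meiotic prophase genes, REC8 rose and HORMAD1 (-0.51) and SYCP3, a synaptonemal complex gene (11.4 ± 0.687 to 8.52 ± 1.46 FPKM), fell (1 rose and 1 fell adjusted over the list alone), and camera gave an adjusted p of 0.407. SYCP3 had a limma adjusted p of 0.0461, which was 0.13, 0.0897 and 0.138 without control replicates 1, 2 and 3 and 0.129 without RA replicate 1; edgeR, added after seeing the data, gave an adjusted p of 0.0833. HORMAD1, at 0.0193, had 0.0581, 0.0715 and 0.0639 without control replicates 1, 2 and 3 and 0.060 without RA replicate 1. Of 8 spermatid genes, 0 passed, and the smallest limma adjusted p was that of SPACA1 (0.393); the list's camera adjusted p was 0.847. Of 13 genes of pluripotency and primordial germ cells, PDPN (1.36) and TFAP2C (0.42) rose and KLF4 (-1.16), SOX2 (-0.64) and PRDM1 fell (camera adjusted p = 0.362). TFAP2C had limma adjusted p-values of 0.107 without control replicate 2, 0.0957 without control replicate 3 and 0.0703 without RA replicate 1.

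Sertoli cell genes moved in both directions. The Sertoli cell gene CLU was at 9242 ± 233 FPKM in control and 9727 ± 342 in RA (limma adjusted p = 0.659); CLU was named after its values were seen. Of 20 Sertoli cell genes, 7 rose and 9 fell (8 and 10 adjusted over the list alone), with no call for the list (camera adjusted p = 0.817) a median (-0.048) and test direction that were lower and a mean (0.035) that was higher. SOX9, the factor that specifies Sertoli cells, fell from 48.9 ± 3.19 to 37.8 ± 0.288 FPKM and the intermediate filament VIM from 1129 ± 53.3 to 598 ± 40.0, while CITED1 rose from 87.5 ± 7.33 to 339 ± 55.0 and the inhibin subunit INHBB from 14.1 ± 0.428 to 31.7 ± 1.61 (limma adjusted p at most 0.00588). Among other falls, named after their values were seen, were the KIT ligand KITLG (6.41 ± 0.489 to 1.70 ± 0.959 FPKM), GDNF (9.99 ± 0.373 to 6.59 ± 0.202), AMH (107 ± 16.4 to 64.3 ± 3.95) and the FSH receptor FSHR (40.4 ± 1.91 to 23.4 ± 3.04), with limma adjusted p-values of at most 0.00401.

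Contractile and matrix genes of peritubular myoid cells and fibroblasts were called higher as a list: 13 of 23 rose and 5 fell (camera adjusted p = 0.0132, and adjusted p = 0.703 with an estimated correlation), or 14 and 6 adjusted over the list alone. The smooth muscle actin ACTA2 rose from 225 ± 25.3 to 786 ± 90.0 FPKM, TAGLN from 189 ± 12.8 to 529 ± 36.1 and DCN from 38.9 ± 4.11 to 293 ± 22.0, while S100A4 fell from 120.1 ± 3.12 to 36.7 ± 3.97 (limma adjusted p at most 4.11e-05). The other 4 falls were in PDGFRA, SPARC, POSTN and THY1. Of 12 Leydig cell and steroidogenic genes, CYP11A1 (0.61) and CYB5A (0.96) rose and 4 fell, HSD17B3 and NR4A1 (-0.62, typed pseudo in the deposited table) among them, with no call (camera adjusted p = 0.922). The list's median (0.060) was higher, and its mean (-0.22) and the direction of the test were lower. STAR, which brings cholesterol into mitochondria, was at 1.53 ± 0.313 and 2.00 ± 0.00445 FPKM (limma adjusted p = 0.131). Of 13 endothelial genes, ENG (0.75) and SOX18 (0.39) rose and EMCN (-0.96) and ERG (-0.62) fell (camera adjusted p = 0.922). SOX18 lost its call without each library but RA replicate 1, with limma adjusted p-values from 0.0605 (without RA replicate 2) to 0.150 (without control replicate 2).

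Interferon response genes had the smallest p-value of the 27 lists at camera's preset correlation, while cholesterol biosynthesis had the smallest with an estimated correlation (unadjusted p = 0.0142) and with fry (unadjusted p = 1.10e-05). Of 27 measured members 15 rose and 0 fell (camera adjusted p = 4.13e-06, and adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone, 16 rose and 0 fell. The guanylate-binding protein gene GBP1 rose from 8.48 ± 0.507 to 17.8 ± 0.710 FPKM, the immunoproteasome subunits PSMB8 from 21.2 ± 1.48 to 39.2 ± 4.07 and PSMB9 from 13.3 ± 0.783 to 23.1 ± 3.89, and the interferon regulatory factor IRF7 from 12.0 ± 0.350 to 20.6 ± 1.89 (limma adjusted p at most 0.00340). Of 21 inflammatory cytokine and chemokine genes, 8 rose and IL33, IL18 and TNF fell (camera adjusted p = 0.00557, and adjusted p = 0.703 with an estimated correlation). Adjusted over the list alone, these counts were 9 and 3. The chemokines CCL20 rose from 13.3 ± 1.09 to 80.2 ± 9.26 FPKM, CCL2 from 161 ± 26.6 to 454 ± 16 and CXCL12 from 27 ± 1.51 to 50.6 ± 0.899, and the adhesion molecule ICAM1 from 39.2 ± 2.31 to 84.8 ± 6.18 (limma adjusted p at most 0.000111). Of 18 macrophage and leukocyte markers, 5 rose, including the complement genes C1QA (0.86) and C1QB (1.08) and the antigen-presentation gene CD74 (0.59), and CD86 (-0.87) fell. The list was not called (camera adjusted p = 0.0754), but its camera adjusted p was 0.00703 without RA replicate 1 and 0.0163 with no filter on low values. With all libraries it was 0.703 with an estimated correlation, and fry gave 0.167. Adjusted over that list alone, 6 rose and 1 fell.

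Cholesterol biosynthesis genes were called lower as a list: 11 of 23 fell and 2 rose, DHCR7 among them (camera adjusted p = 0.00151, and adjusted p = 0.383 with an estimated correlation), or 12 fell and 2 rose adjusted over the list alone. HMGCS1, which forms HMG-CoA, fell from 158 ± 12.6 to 55.0 ± 7.64 FPKM (limma adjusted p = 9.07e-05), MSMO1 from 84.7 ± 0.390 to 45.8 ± 2.84 (8.58e-05) and CYP51, the older symbol of CYP51A1, from 112 ± 5.08 to 68.6 ± 2.57 (0.000234). Of 27 glycolysis and hypoxia genes, 7 fell, the glucose transporters SLC2A1 (-0.62) and SLC2A3 (-0.53) and the hexokinase HK1 (-0.41) among them, and TPI1 (0.39) and HK2 rose. That list was not called (camera adjusted p = 0.253), but fry gave an adjusted p of 0.0225 in the lower direction. Adjusted over the list alone 9 fell and 4 rose.

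The oxidative phosphorylation list was called higher (camera adjusted p = 0.0424, and adjusted p = 0.703 with an estimated correlation), although 4 of 25 members rose and 0 fell, and 0 passed adjusted over the list alone. The 4 genes were ATP5A1 (0.26), ATP5G1 (0.30) and the rows LOC100525869 (0.41) and LOC100156879 (0.27), whose best human matches are CYC1 and UQCRC1. The camera adjusted p was 0.0762 without control replicate 2, 0.0553 without control replicate 3, 0.174 without RA replicate 2, 0.0659 without the variance trend, 0.273 after quantile normalization, 0.155 with array weights and 0.486 after the correction for gene length. Each of the 4 genes lost its call (limma) without control replicate 2, with adjusted p-values from 0.0921 to 0.143, and without control replicate 3, from 0.0816 to 0.116. ATP5A1, ATP5G1 and LOC100156879 also lost it without control replicate 1 (0.108, 0.0716 and 0.0961), ATP5A1 and ATP5G1 without RA replicate 1 (0.0617 and 0.0623) and LOC100156879 without RA replicate 3 (0.0571). Of the 13 genes of the mitochondrial genome, 0 passed, ND5 having the smallest limma adjusted p (0.236), and camera gave an adjusted p of 0.407.

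ERK and FGF feedback genes were called lower (camera adjusted p = 0.0424, and adjusted p = 0.703 with an estimated correlation): SPRY2 (112 ± 10 to 58.8 ± 2.35 FPKM), DUSP4 (99.3 ± 2.11 to 58.5 ± 8.84), ETV1 (16.8 ± 1.25 to 6.40 ± 2.01), EGR2 (7.35 ± 0.456 to 4.71 ± 0.197) and DUSP5 fell and IER3 rose among 20 members, while 7 fell and 1 rose adjusted over the list alone. The limma adjusted p of SPRY2, DUSP4, ETV1 and EGR2 was at most 0.00343. The camera adjusted p was 0.118 without control replicate 1, 0.0525 without RA replicate 2, 0.100 with array weights and 0.0810 after the correction for gene length.

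The remaining lists were not called by camera. BMP, TGF-beta and activin genes (adjusted p = 0.847) included BAMBI (0.72) and ID1 (0.76) among 6 of 22 that rose and CTGF, encoding CCN2 (-0.60), among 3 that fell, with a lower median (-0.0087) and a higher mean (0.0010) and test direction. WNT genes (camera adjusted p = 0.623, median -0.091 and test direction lower, mean 0.17) included rises of WNT6 and LGR5 (1.22) and 4 falls of 19, DKK3 (-0.82) and LEF1 (-0.48) among them. Extracellular matrix genes moved both ways, with 9 of 32 higher, such as LOXL2 (1.46) and THBS2 (1.11), and 10 lower, such as LAMA1 (114 ± 12.7 to 25.4 ± 2.79 FPKM) and TNC (-1.38), with camera adjusted p = 0.847, a median of 0.029 and test direction higher, and a mean of -0.070. Of 20 stress genes (camera adjusted p = 0.407, but fry adjusted p = 0.0207 in the lower direction), 5 rose and 6 fell, including NQO1 (-1.27), ATF3 (-0.92) and SRXN1 (-0.62), and HERPUD1 (0.38) rose. Of 19 p53 targets and apoptosis genes (0.407), 6 fell, GADD45A (-0.82), CDKN1A (-0.62) and BTG2 (-0.39) among them, and 3 rose, PHLDA3 (0.85) with the smallest p. Adjusted over each list alone, the counts of genes that rose and fell were 6 and 3 for BMP, TGF-beta and activin, 2 and 5 for WNT, 14 and 12 for extracellular matrix, 6 and 7 for stress and 5 and 6 for p53 genes.

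Of 29 cell cycle genes, MCM7 (0.30) and BIRC5 (0.56) rose, 0 fell, 0 passed adjusted over the list alone, and the list was not called (camera adjusted p = 0.392). The proliferation marker MKI67 was at 1.53 ± 0.339 FPKM in control and 1.89 ± 0.407 in RA (limma adjusted p = 0.341). Without control replicate 2 the limma adjusted p of MCM7 was 0.0711 and that of BIRC5 0.135, and without control replicate 1 they were 0.0638 and 0.106. MCM7 also lost its call without control replicate 3 (limma adjusted p just over the threshold) and BIRC5 without RA replicate 3 (limma adjusted p = 0.0537). Of 12 DNA methylation genes, TET3 (-0.54) and MBD2 (-0.26) fell and 0 rose (camera adjusted p = 0.358). TET3 had limma adjusted p-values of 0.0557 without control replicate 2 and 0.0557 without control replicate 3. MBD2 lost its call without each library but RA replicate 2, with limma adjusted p-values from 0.0543 (without RA replicate 3) to 0.120 (without control replicate 2).

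**Figure D3:**
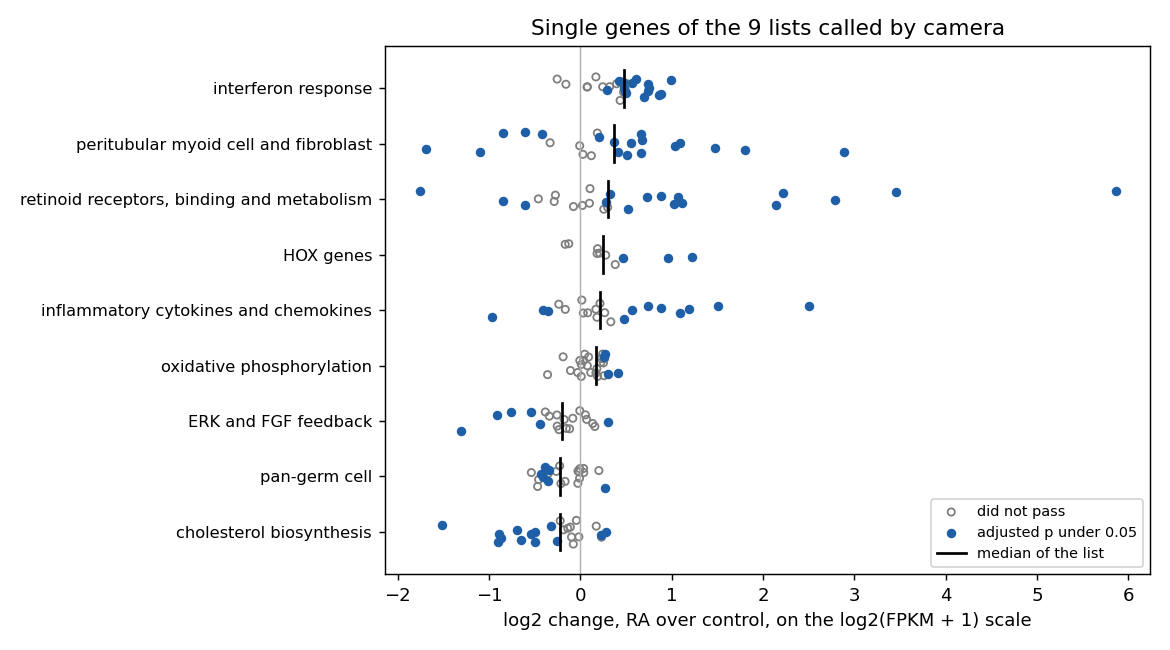
Log2 changes (RA over control, log2(FPKM + 1) scale) of the measured members of the 9 lists called by camera; filled points passed limma at adjusted p under 0.05, open points did not, and black lines mark list medians. The medians run from -0.22 for cholesterol biosynthesis to 0.47 for interferon response, and members of most lists lie on both sides of 0.

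Long non-coding RNAs (lncRNAs) were taken as the rows typed ncRNA, pseudo or miscRNA of at least 200 bases. Of 794 kept, 63 were higher and 39 lower in RA (limma, adjusted over all genes), and 34 and 19 passed when adjusted over the lncRNAs alone. Rows typed ncRNA made up 50 of the higher and 33 of the lower, and the others include NR4A1, a gene of the steroidogenesis list typed pseudo. The balance turned with no filter on low values (80 higher and 98 lower) and after the correction for gene length (50 higher and 65 lower). Leaving out a library took the higher count to 40 without control replicate 2, 40 without control replicate 3 and 34 without RA replicate 1, and the lower count to 24 without control replicate 1, 16 without control replicate 2 and 24 without control replicate 3. LOC106506838 (chromosome 18, 45473363 to 45477416) rose from 0.669 ± 0.409 to 5.92 ± 1.22 FPKM (limma adjusted p = 0.000295), LOC106510642 (chromosome 6, 88108583 to 88114948) from 0.921 ± 0.0605 to 4.28 ± 0.304 (4.80e-05), and the row KRT7, typed ncRNA in the deposited table although the symbol is that of a keratin, from 11.1 ± 0.419 to 26.8 ± 0.939 (2.95e-05). The largest falls were those of LOC106506514 (log2 change -1.03, limma adjusted p = 0.000326), which had 71, 91 and 83 reads in control replicates 1, 2 and 3 and 5, 1 and 0 in RA replicates 1, 2 and 3, LOC110259500 (-0.94, 0.00132) and LOC106505568 (-0.92, 0.00115). LOC106505568 overlaps CSRNP1 on the opposite strand, and since the strand setting of the counting is not given in the sources used here, reads of the pair cannot be told apart.

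The authors' deposited tables list 4377 genes as changed, 2335 up and 2042 down in RA, all at an FDR under 0.05. Of these, 4056 were kept here. Among the 4056, 3524 (86.9%) were called here in the same direction and 0 in the opposite one. Another 245 genes called here were not in the authors' deposited tables. The shared calls numbered 2152 without control replicate 2 and 2276 without control replicate 3. The authors' calls rest on the same 6 libraries and are not independent evidence. The authors' deposited table of non-coding genes holds 182 rows, 87 up and 95 down. Of these, 102 were kept here and 84 were called in the same direction. In the authors' deposited table the log2 fold change of DHRS3 is 6.71, of CYP26A1 6.35, of STRA8 1.74 and of IGFBP5 -3.94. These values are not on the log2(FPKM + 1) scale used here, on which CYP26A1 changed by 3.45 at a ratio of mean FPKM of 80.8. KIT, SOHLH1, DNMT3B, UCHL1, NANOS2, STAR, MKI67 and SYCP3 have no row in the authors' deposited tables used here.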

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

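The alternatives edgeR, DESeq2, length correction and no minimum length were chosen after seeing the data. The counts of genes, lncRNAs, lists and shared calls stayed within 1.5 times the reported value in 110 of 141 alternatives. Of 3300 values of named genes under alternatives, 3094 kept their side of the threshold, 183 lost a call, 23 gained one and 0 turned sign with a call. Of 486 values of lists, 444 kept their side of the threshold, 32 lost a call, 10 gained one and 0 turned sign with a call. For genes and lists, a change of sign without a call in either fit was counted among those that kept their side. No scaling moved the median of all genes by over 0.1. Array weights, whose fit stopped short of its tolerance and gave RA replicate 1 a weight of 6.67 and RA replicate 2 one of 0.169, raised the counts to 3410 higher and 3621 lower genes and 141 higher and 122 lower lncRNAs. Requiring a log2 change of at least 1 as well left 177 higher and 212 lower genes and 4 higher and 1 lower lncRNAs. It left 380 of the authors' calls, since it adds a condition on the log2(FPKM + 1) scale. On that scale LOC110259500 and LOC106505568 stayed short of it, although their ratios of mean FPKM of control over RA were 2.81 and 3.32. With no filter 80 lncRNAs were higher and 98 lower, with a filter of mean FPKM 0.1 there were 78 and 75, and with mean FPKM 1 there were 47 and 23, as the number of rows tested changed. After the length correction 50 lncRNAs were higher and 65 lower, and 1 list was lower; the cause was not tested. Camera with an estimated correlation called 0 higher and 0 lower lists (unadjusted p under 0.05 in 1 list, cholesterol biosynthesis). Camera without the variance trend called 5 higher and 3 lower lists, without oxidative phosphorylation (adjusted p = 0.0659). Fry, which does not compare a list with other genes, called 6 lower and 5 higher lists, and quantile normalization gave 5 lower lists; the cause was not tested. Leaving out each library in turn gave 1201 to 2248 higher and 992 to 2258 lower genes, 34 to 72 higher and 16 to 54 lower lncRNAs, 2152 to 3618 of the authors' calls, 4 to 6 higher and 2 to 3 lower lists, with fewer libraries in each fit; the highest gene counts came without RA replicate 2. edgeR called 1965 higher and 1685 lower genes and DESeq2 2274 and 2165.

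Replicate numbers are shared between the groups, and the labels do not say whether they pair the libraries. The deviations of same-numbered libraries from their group means correlated at -0.21, -0.086 and 0.34 for numbers 1, 2 and 3. With 3 libraries per group these values do not decide whether the numbers pair the libraries. With the replicate number as a block, 1610 genes were higher and 1405 lower, 52 lncRNAs higher and 27 lower, 7 lists higher and 3 lower, and 2896 of the authors' calls were shared. A choice of the highest row per gene was not run, since each gene has 1 row. Robust moderation and a fold threshold were not run for lists, since camera takes neither, and edgeR and DESeq2 were not run for lists. At these depths of 62084199 to 87520891 reads the spread between libraries, not counting error, limits most named values, and genes under a mean of 0.5 FPKM were tested only under the lower filters.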

Other observations

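The tests of germ cell share and of macrophage markers, the length correction, all gene families and the single genes of this part outside the naming rule (KRT8, KRT19, KRT80, C3, CFI, LBP, S100A8, PSMB10, KLF2, CAV1, CAV2, FABP5, RPL3, RPS2 and C1QC) were chosen after the result was seen. Keratin genes rose in 6 of 7 measured members, among them KRT8 (59.5 ± 9.97 to 192 ± 13.8 FPKM), KRT19 (11 ± 2.59 to 32.8 ± 4.80) and KRT80 (10 ± 0.847 to 27.9 ± 2.35), with limma adjusted p-values of at most 0.000777. The 6 include the row KRT7, which is typed ncRNA and was also counted among the lncRNAs above. Keratins 8 and 19 form filaments of simple epithelia. The complement component C3 rose from 738 ± 44.3 to 2192 ± 420.4 FPKM, its regulator CFI from 5.94 ± 0.230 to 23.5 ± 2.68, the lipopolysaccharide-binding LBP from 0.391 ± 0.0331 to 3.88 ± 1.17 and the calprotectin subunit S100A8 from 3.35 ± 0.270 to 16.9 ± 4.58 (limma adjusted p at most 0.000289). Of 18 chemokine genes of the CCL, CXCL and CX3CL families, 10 rose and 0 fell, and the same counts were found after the length correction. The immunoproteasome subunit PSMB10 rose from 53.9 ± 0.887 to 138 ± 27.8 FPKM (limma adjusted p = 0.000325).

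Of 14 measured Kruppel-like factor genes, 7 fell and 0 rose (limma), KLF4 and KLF2 (47.0 ± 7.95 to 23.6 ± 2.82 FPKM) among them, and 7 fell after the length correction. The caveolin genes CAV1 (48.5 ± 1.93 to 15.6 ± 2.16 FPKM) and CAV2 (6.77 ± 1.08 to 2.35 ± 0.989) and the fatty acid binding protein gene FABP5 (192 ± 23.0 to 63.7 ± 3.87) fell (limma adjusted p at most 0.00668). Of the 10 measured EXOSC genes of the RNA exosome, 6 rose and 0 fell (5 rose after the length correction), and of 18 PSMA and PSMB proteasome genes 11 rose and 0 fell, or 5 after the length correction.

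With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split called 3769 genes, 102 lncRNAs and 9 lists; the highest of the other splits called 0 genes, 0 lncRNAs and 9 lists, so that 1 of 10 splits called as many genes, 1 of 10 as many lncRNAs and 2 of 10 as many lists. The other split with 9 lists set control replicates 1 and 2 and RA replicate 2 against the rest. Each of the other splits called between 1 and 9 lists. The 0 genes of the other splits are limma calls. Each of those splits has RA libraries on both sides, so the RA difference adds to the spread within a side. Their 0 calls therefore do not measure the rate of false calls.

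Ribosomal protein genes of the large and small subunit rose in 66 of 82 measured members and fell in 0 (limma), with a median log2 change of 0.40; RPL3 went from 676 ± 19.5 to 1001 ± 87.5 FPKM and RPS2 from 271 ± 5.67 to 415 ± 51.2. Most of these genes are short (median 750 bases), although the deposited length of RPS2 is 5903 bases, and a length trend between libraries was weighed first. Among 10000 lists matched on length and mean level, the median lay at the 100th percentile, above the highest matched median of 0.30, although matched genes were less abundant (median log2 level 8.64 against 9.31), and 60 rose after the length correction with a median of 0.27. The matched lists were drawn gene by gene, which leaves out any correlation among ribosomal protein genes, so the percentile does not exclude a shared trend. RA replicate 2 alone does not account for the rise, since the median without that library was 0.31 and 66 rose. A response of translation genes to RA may underlie the rise; reads shared with ribosomal pseudogenes and a trend among short, highly abundant transcripts were not tested and stay open.

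Undifferentiated spermatogonia genes fell in 10 of 30 members, with a median of -0.48 over these 10, while the median of the whole list was -0.088 and the list was not called. After the length correction the median over these 10 was -0.46, so it hardly changed, and 8 of them still passed limma. The 10 had been picked for falling, so this describes only these genes and decides nothing for the list. The changes of GFRA1 (-0.45 to -0.27) and ZBTB16 (-0.42 to -0.27) shrank and no longer passed, and the list's camera adjusted p went from 0.102 to 0.168. Fewer germ cells in the RA cultures stays open: the pan-germ list was called lower (camera adjusted p = 0.0424), but not with an estimated correlation (0.703), after the length correction (0.0656), or without control replicate 2 (0.0733), control replicate 3 (0.0531), RA replicate 1 (0.0698) or RA replicate 3 (0.0691). Its median minus that of the undifferentiated list was -0.13, which decides nothing, since the undifferentiated list was not called and single pan-germ genes had an SD of 0.23; a first version, which set the pan-germ median (-0.22) against the 10 genes that fell and spoke against fewer germ cells, was replaced after its result because those 10 had been picked for falling. A loss of the undifferentiated state in RA, the contrast of the design, may act as well and was not told apart from fewer germ cells. Which cells the falling genes come from was not tested. THY1, which fell, is also in the peritubular myoid cell and fibroblast list, and the Sertoli cell gene CLU was at a mean of 9242 FPKM in control.

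Interferon response genes had a median log2 change of 0.47 over 27 members. RA replicate 2 alone does not account for the rise: without it the list's median was 0.52 and 19 members passed limma. More macrophages in the RA cultures stays open, since the macrophage markers moved apart. The 6 most abundant in control (TYROBP, CD14, CD68, SPI1, FCER1G and LAPTM5, at 6.06 to 24.8 FPKM) had a median of 0.13 and an SD of 0.083 (difference from the interferon list -0.34). But C1QB (1.08), C1QC (0.95), C1QA (0.86) and CD74 (0.59) rose by more than the interferon median. The macrophage list was called without RA replicate 1 (camera adjusted p = 0.00703) and with no filter on low values. It was not called in the main fit (0.0754) or with an estimated correlation (0.703). A first version set the 6 markers against the called interferon genes (median 0.61) and was replaced after its result, because those genes had been picked for rising. A changed state of macrophages or other cells and a direct response to RA may each fit and were not tested.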
